A study of Mus musculus with 4 samples.

How the data were processed

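DNA of mouse 46C embryonic stem cells (ESC) and of neural progenitor cells (NPC) made from them was profiled for 5-hydroxymethylcytosine (5hmC) by immunoprecipitation of denatured DNA with a 5hmC antibody and sequencing (hMeDIP-seq). There were 4 libraries: a 5hmC library and an input library for each of the 2 cell types, with 1 library per group. Per the labels' protocols, sonicated DNA of each cell type (fragments under 500 bp) was ligated to an adaptor with its own barcode, about 4 µg of each was mixed in a single tube, 10% was taken off as input, and the rest was precipitated with 4 µg of antibody. The products and the input were amplified for 10 to 12 cycles. Because both barcodes shared a tube, the share of antibody-bound reads that carried each barcode, divided by its share in the input, measures 5hmC of NPC relative to ESC.

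Each deposited file lists read positions on genome build mm9, and Bowtie 0.12.7 is named as the aligner per the submitters' processing notes. The files have no header. In the deposited files each line is a read position on a strand, extended to 350 bp, and its last numeric column is a whole-number count from 1 up to 307, taken here as the raw read count at that position because a start and strand occurred on a single line, apart from 1 to 46 lines per file. These counts were not scaled to depth or to input by the authors, as far as the values show. The treatment of reads with several matches and any filter on mapping quality are not given in the sources used here. Between 97.9% and 99.7% of positions held 1 read.

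Everything below was computed from these positions with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The genome-wide and chromosome values used all deposited reads on chromosomes 1 to 19 and X. The main measure was the number of 5hmC reads per input read in each cell type, and the NPC/ESC ratio of the 2 values. The level itself depends on how deeply the 5hmC and input libraries were sequenced, so that only its ratio between cell types or between regions can be read. Tiles of 5 kb used distinct reads, meaning at most 1 read per position and strand, placed by the midpoint of the extended read. Tiles with fewer than 5 reads in the summed inputs, or with more than 5 times the median of 23 reads, were left out, which kept 476819 of 527795 tiles. A tile was called enriched in a cell type at 10 or more 5hmC reads and a ratio of 5hmC to own input of at least 2, after scaling each library to its distinct reads and adding a pseudocount of 0.5 reads. Among tiles enriched in either cell type, a fold of 2 in the NPC/ESC ratio was counted around 1, which keeps the global difference. It was also counted around the genome-wide ratio, which sets that difference aside.

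With 1 library per group there was no replicate error, and no p-values were computed. These are fixed rules of size that compare libraries, not conditions. Intervals are 95% intervals: exact conditional intervals of the odds ratio, the usual normal approximation on the log scale where a count passed 2000, and exact (Clopper-Pearson) intervals for ratios of 2 counts. They cover counting error only, and PCR copies are not independent molecules. Intervals of named tiles are not adjusted for the selection of these tiles as extremes. Where a count was 0, the upper limit of the interval is given in place of a fold. Beside the counts of enriched and of differing tiles in the main setting stand the numbers obtained from simulated Poisson or binomial draws. No draws were made for the alternative settings. To avoid selecting on noise, reads of each tile were also split at random into 2 parts, tiles were chosen on the first part and values taken from the second. The minimum of 5hmC reads for a call on such a part was 5, and 10 as an alternative, with the pseudocount as above.

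The tile calls were tested on simulated data over 476819 tiles with known folds. With 200 tiles per setting and a true fold of 3, 84.5% of tiles changed in ESC alone were called in ESC, and 46% of those changed in NPC alone were called in NPC. With a true fold of 6 in NPC the share called was 85.5%. Of unchanged tiles, 4.39% were called in ESC and 0.945% in NPC. The lower depth of the NPC 5hmC library (3.63 distinct reads per kept tile, against 14.9 in ESC) therefore leaves NPC enrichment of 3-fold often uncalled.

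The comparisons, their alternatives and the rule for named tiles were fixed before the data were examined. The named tiles had at least 20 distinct reads in a 5hmC library and at least 20 in each input. They were the 5 highest and 5 lowest NPC/ESC ratios whose interval excluded the genome-wide ratio, and the 5 highest ratios of 5hmC to input in each cell type. Promoters, gene bodies, CpG density and 15 gene lists had also been planned. They were left out because no mm9 sequence or annotation was used here and coordinates of another build cannot be mixed with these reads, so that regions are given by position without gene names. GC content could not be checked for the same reason. Alternatives covered tile size, read counting, background, fold, read minimum, read placement, pseudocount and depth. Windows of 1 Mb (at least 500 reads in each input, summed over kept tiles) the omission of tiles with reads mostly on 1 strand, the 10 bins, the runs of adjacent tiles, the counts per strand, the subtraction of an equal background from both cell types and the random split of reads were added after seeing the data.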

Results

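Genome-wide 5hmC, the oxidation product of 5-methylcytosine formed by TET enzymes, was compared between mouse ESC and NPC. The cells were of the 46C line, which reports Sox1 expression by GFP and was grown with serum and leukemia inhibitory factor. The NPC were Sox1-GFP-positive rosette-like cells at day 9 of monolayer neural differentiation. A 5hmC library and an input library were sequenced from each cell type, without replicates. The ESC 5hmC library held 7291825 reads and the ESC input 5106976. The NPC 5hmC library held 1776959 reads and the NPC input 6637930. Positions are on genome build mm9, and no annotation of that build was used here.

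The first comparison asked how much 5hmC NPC carried relative to ESC across the genome. 5hmC was lower in NPC. On chromosomes 1 to 19 and X, 1.43 5hmC reads were obtained per input read in ESC (95% interval 1.43 to 1.43) and 0.268 in NPC (0.267 to 0.268). The NPC/ESC ratio was 0.187 (0.187 to 0.188), a 5.34-fold lower level in NPC (5.33 to 5.35). The intervals cover counting error only, and the spread between cultures or immunoprecipitations is unknown. The ratio also depends on background that was not measured: it was 0.0852 after subtracting 0.160 reads per input read from both cell types, the NPC level in the tiles poorest in ESC 5hmC, and 0.0364 after subtracting 0.224, the level on mitochondrial DNA. The latter exceeds the NPC level in those poorest tiles (0.158 to 0.161), and would leave less than 0 there.

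The lower level in NPC was found on each of the 19 autosomes and on chromosome X. Among autosomes the NPC/ESC ratio ran from 0.162 (0.161 to 0.163) on chromosome 11 to 0.215 (0.213 to 0.217) on chromosome 3. Chromosome X had the highest ratio, 0.314 (0.310 to 0.319), and the lowest ESC level, 0.711 5hmC reads per input read. It was poor in 5hmC in both cell types. Its 5hmC per input was 0.497 of the genome-wide level in ESC (0.493 to 0.502) and 0.834 in NPC (0.824 to 0.844). Autosomes spread from 0.826 to 1.22 of the genome-wide level in ESC, with chromosomes 11, 19, 17, 5 and 4 highest (1.22, 1.19, 1.18, 1.17 and 1.15). In NPC they spread from 0.942 to 1.09, with chromosome 5 highest. The input libraries gave the background of this comparison. The NPC/ESC ratio of their chromosome shares lay between 0.985 (0.981 to 0.989, chromosome 2) and 1.02 (1.01 to 1.02, chromosomes 3 and 14), so that each chromosome's share of the input reads differed by less than 2% between cell types.

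**Figure D1:**
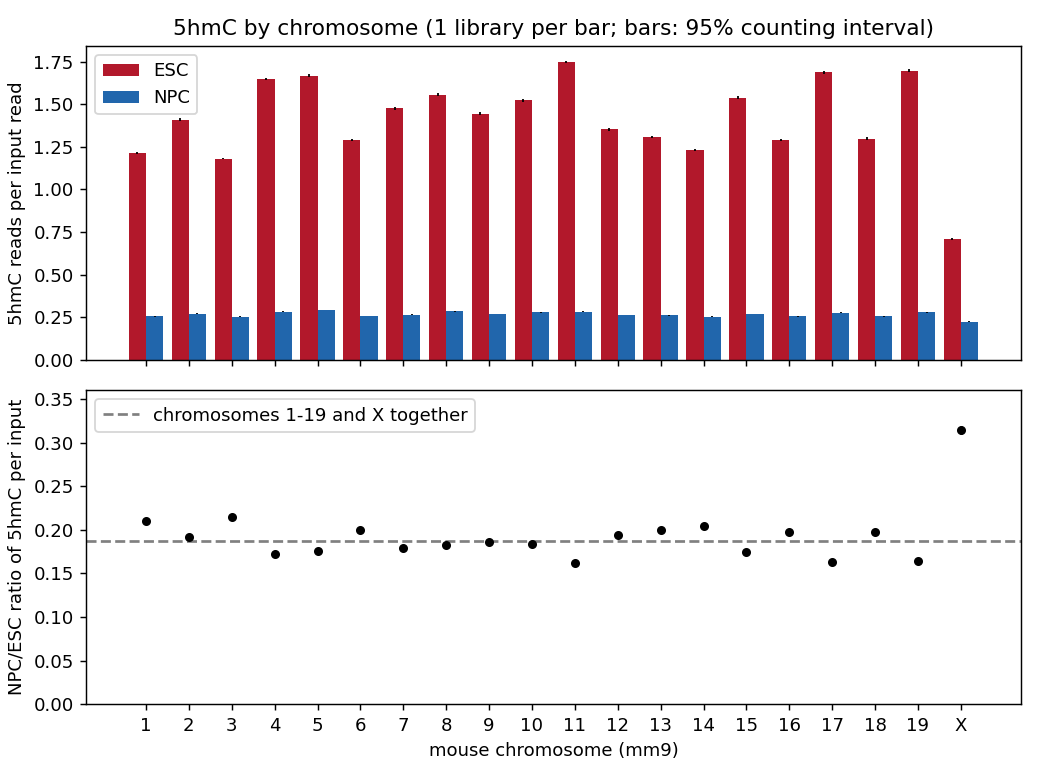
5hmC reads per input read in ESC and NPC (upper panel, bars, 1 library each) and the NPC/ESC ratio (lower panel, points) for each chromosome, with 95% counting intervals. The ratio lies between 0.162 and 0.215 on autosomes and at 0.314 on chromosome X.

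At the scale of 1 Mb, NPC were lower than ESC in all 2501 windows measured, and the interval lay below 1 in 2500 of them. The exception in the interval was 84000001 to 85000000 on chromosome X, with a ratio of 0.871 (0.656 to 1.16) from 112 ESC and 134 NPC 5hmC reads. The window with the lowest ratio was 76000001 to 77000000 on chromosome 15, at 0.0888 (0.0823 to 0.0957). The 5th to 95th percentile of windows ran from 0.339 to 2.59 5hmC reads per input read in ESC, a 7.63-fold span, and from 0.175 to 0.358 in NPC, a 2.05-fold span. The 2 profiles ran in parallel, with a Pearson r of 0.804 on the log2 scale and a Spearman rho of 0.824 across windows. Windows are not independent replicates. Part of each value is counting noise, and the median window held an NPC/ESC ratio of 0.238.

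**Figure D2:**
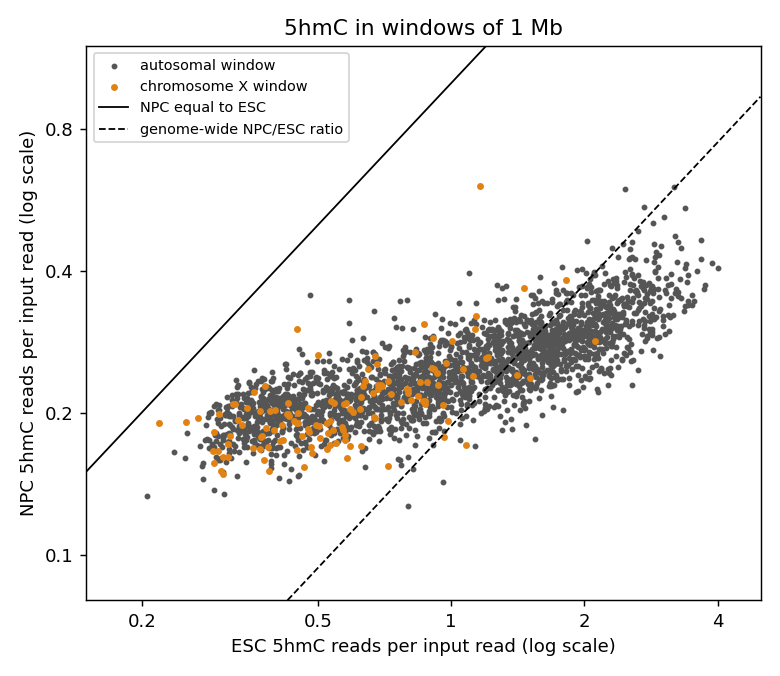
5hmC reads per input read in NPC against ESC for 2501 windows of 1 Mb, both on log scales, with chromosome X windows in orange. All points lie below the line of equal values, and the NPC range is narrower than the ESC range.

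The richest ESC windows lay on chromosome 5 from 114000001 to 115000000 (4.00 5hmC reads per input read, 3.86 to 4.15) and on chromosome 4 from 140000001 to 141000000 (3.89, 3.74 to 4.04). In NPC these had 0.407 (0.385 to 0.429) and 0.415 (0.392 to 0.439). The richest NPC windows were 166000001 to 167000000 on chromosome X (0.604, 0.535 to 0.682) and 123000001 to 124000000 on chromosome 8 (0.604, 0.576 to 0.633). The X window reached 1.16 in ESC (1.03 to 1.30) and the chromosome 8 window 3.19 (3.07 to 3.31). The X window was thinly covered, with 538 ESC and 715 NPC input reads. A single 5 kb tile in it, from 166435001 to 166440000, held 140 of its 432 NPC 5hmC reads and 42 of its NPC input reads. The plus strand held 86.4% of the NPC 5hmC reads in that tile. The rank of the X window therefore rests in part on that tile.

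The NPC/ESC ratio was lower where ESC were rich in 5hmC. Tiles of 5 kb were sorted into 10 bins by ESC 5hmC in a random part of the reads and measured in the other part. The ESC level rose 11.1-fold from the poorest to the richest bin, from 0.311 (0.309 to 0.314) to 3.46 (3.45 to 3.48) reads per input read. The NPC level rose 2.41-fold, from 0.160 (0.158 to 0.161) to 0.385 (0.383 to 0.388). The NPC/ESC ratio fell from 0.512 (0.505 to 0.520) to 0.111 (0.111 to 0.112), and each bin in between lay between these values. The ratio of chromosome X was that of tiles with a like ESC level. With distinct reads its ESC level was 0.703 and its ratio 0.315. Bins 4 and 5, counted from the poorest, had ESC levels of 0.605 and 0.817 and ratios of 0.346 and 0.288.

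**Figure D3:**
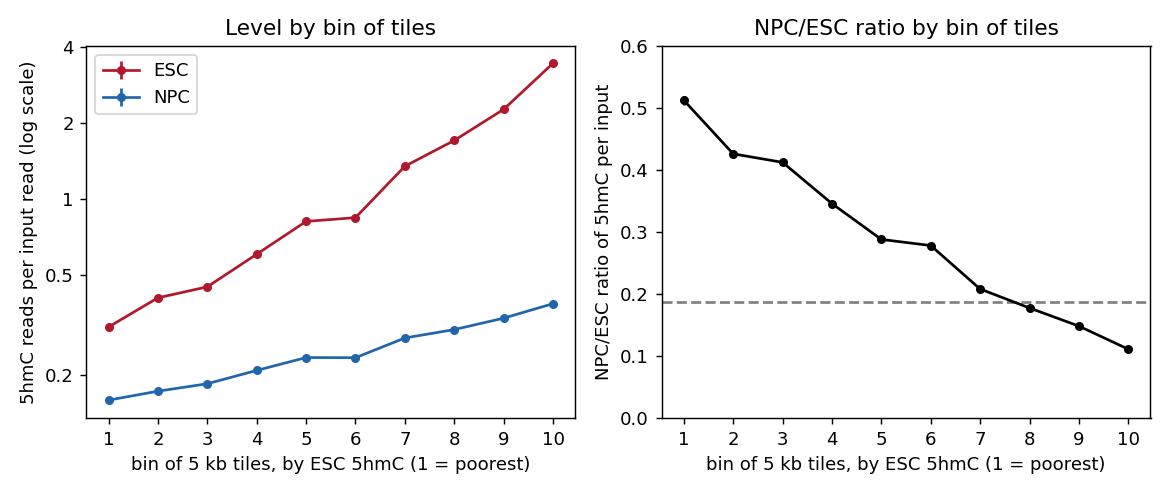
5hmC reads per input read (left, log scale) and NPC/ESC ratio (right, dashed line at the genome-wide ratio of 0.187) in 10 bins of 5 kb tiles ordered by ESC 5hmC. Bins were set on a random part of the reads and values come from the rest, with 95% counting intervals smaller than the points; the ratio falls from 0.512 to 0.111.

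The second comparison asked where each cell type was enriched. In ESC 50527 tiles (10.6% of those kept) were enriched at least 2-fold over input, and in NPC 27754 (5.82%). Poisson draws without any enrichment gave 20694 tiles in ESC and 4571 in NPC. Both cell types were enriched in 10396 tiles, against 2941 for independent lists of these sizes. Binomial draws with the genome-wide NPC/ESC ratio in every tile gave 24900 tiles enriched in both, so that the observed overlap lay above that of independent lists and below that of a single shared profile. The 10396 observed tiles made up 37.5% of the NPC tiles and 20.6% of the ESC tiles. The share of tiles enriched was highest on chromosome 11 in both cell types (15.9% in ESC and 8.82% in NPC). It was lowest on chromosome X (2.40% and 0.506%), which was also covered less. Chromosome X had 23910 kept tiles and 114949 distinct ESC input reads, against 23209 and 307782 on chromosome 11. The fixed minimum of 5hmC reads is harder to reach at such depth. The low share on chromosome X therefore does not measure its enrichment alone. After all libraries were thinned to the depth of the NPC 5hmC library, 36564 tiles were enriched in ESC and 24320 in NPC. The counts depended on the rule. Without a minimum of 5hmC reads their order was reversed, with 52174 in ESC and 66650 in NPC. The NPC tiles added there held fewer than 10 5hmC reads each, and no draws without enrichment were made for this setting. With a pseudocount of 5 reads the ESC and NPC counts were nearly equal, at 31802 and 31523. It was added to unscaled counts. NPC had 3.63 5hmC and 13.7 input reads per kept tile, and ESC 14.9 and 10.55. By construction it thus raised NPC enrichment and lowered ESC enrichment in an average tile. Other settings moved the ESC and NPC counts apart: a minimum of 20 reads gave 47836 and 4964, and tiles of 1 kb gave 128304 and 7286. Among tiles enriched in NPC alone with at least 20 NPC 5hmC reads, 22.9% had over 75% of these reads on 1 strand, against 1.18% from binomial draws. This share was 18.7% in tiles enriched in both and 20.6% over all kept tiles with as many reads.

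Tiles were also called on a random part of the reads, with a minimum of 5 in place of 10 5hmC reads, and measured in the rest. These classes are therefore not the tiles counted above. Tiles enriched in ESC alone (45008) had 2.31 times the genome-wide level in ESC (2.30 to 2.32), 1.11 times in NPC (1.10 to 1.12), and an NPC/ESC ratio of 0.0900 (0.0893 to 0.0907). Tiles enriched in both (11809) had 2.67 times in ESC (2.65 to 2.69) and 2.68 times in NPC (2.66 to 2.71), with a ratio of 0.189 (0.187 to 0.191). Tiles enriched in NPC alone (23108) had 1.25 times in ESC (1.25 to 1.26) and 2.22 times in NPC (2.20 to 2.23). Their ratio was 0.332 (0.329 to 0.335), so that as a class these tiles too held less 5hmC per input in NPC than in ESC. With a minimum of 10 reads in that part, the ratios were 0.0990 (0.0983 to 0.0997) for ESC alone (48241 tiles), 0.258 (0.253 to 0.263) for both (3190) and 0.438 (0.428 to 0.447) for NPC alone (3366). Tiles enriched in both then had 2.98 times the genome-wide level in ESC (2.94 to 3.02) and 4.08 times in NPC (4.02 to 4.14). Those enriched in NPC alone had 1.56 and 3.64 times, and those enriched in ESC alone 2.445 and 1.29 times.

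ESC-enriched tiles formed longer stretches. Runs of at least 5 adjacent enriched tiles numbered 1084 in ESC and 97 in NPC, and held 14.0% and 2.02% of the enriched tiles. The longest ESC runs spanned 105 kb, on chromosome 15 from 58790001 to 58895000 and on chromosome 2 from 168450001 to 168555000. Their NPC/ESC ratios were 0.113 (0.0929 to 0.138) and 0.0773 (0.0630 to 0.0950). The longest NPC run spanned 60 kb on chromosome 8, from 123045001 to 123105000. It was enriched 3.74-fold in NPC (3.17 to 4.42) and 4.21-fold in ESC (3.71 to 4.80), with a ratio of 0.167 (0.135 to 0.206). The next NPC run, of 55 kb on chromosome 15 from 83525001 to 83580000, was enriched 3.88-fold in NPC (3.22 to 4.67) and 1.42-fold in ESC (1.19 to 1.70), with a ratio of 0.513 (0.396 to 0.665). Run lengths depend on depth, which was lower in NPC.

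The third comparison counted tiles that differed between cell types. Of the 67885 tiles enriched in either, 57581 (84.8%) were at least 2-fold lower in NPC, 695 (1.02%) at least 2-fold higher and 9609 lay in between. When the same tiles were set against the genome-wide ratio, 28473 (41.9%) lay at least 2-fold below it and 14283 (21.0%) at least 2-fold above it. Binomial draws with a single ratio in every tile gave 8962 below and 6052 above the genome-wide ratio, and 5 tiles at least 2-fold higher in NPC. They also gave 59837 of 62004 tiles at least 2-fold lower in NPC, so that a count of this size follows from the genome-wide difference alone. Which side of the genome-wide ratio held more tiles depended on the settings. With a pseudocount of 5 reads 7978 tiles lay below and 18389 above it. Added to unscaled counts, 5 reads raise the ratio of an average tile by construction, since the NPC 5hmC library had fewest reads per tile. Without a minimum of 5hmC reads 29686 lay below and 45508 above the genome-wide ratio. The number at least 2-fold higher in NPC also moved. It was 9495 without that minimum, 1840 at equal depth, 400 with summed inputs and 79 with a minimum of 20 reads. Tiles called at least 2-fold higher in NPC on a random part of the reads had a ratio above the genome-wide one but below 1 in the rest. It was 0.634 (0.614 to 0.656) with a minimum of 5 reads in that part (2792 tiles) and 0.731 (0.678 to 0.789) with a minimum of 10 (325 tiles). Neither set is that of the 695 tiles.

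The named tiles with the lowest NPC/ESC ratio each had no NPC 5hmC read. The tile from 126445001 to 126450000 on chromosome 10 held 157 ESC 5hmC reads over 22 input reads, a 5.07-fold enrichment (3.23 to 8.32), against 0 over 27 in NPC, and the 95% interval of its NPC/ESC ratio reached up to 0.0231. The tile from 133590001 to 133595000 on chromosome 7 held 122 ESC and 0 NPC 5hmC reads, with an upper limit of 0.0247. The other tiles, on chromosome 8 from 119725001 to 119730000 and on chromosome 13 from 53015001 to 53020000 and from 114385001 to 114390000, had upper limits of 0.0308, 0.0320 and 0.0352. They were selected as extremes among 16567 eligible tiles, which the intervals do not take into account.

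Among the tiles with the highest ratio, those on chromosome 12 from 99800001 to 99805000 (2.91, 1.05 to 8.18) and on chromosome 13 from 77575001 to 77580000 (2.44, 1.003 to 6.05) had intervals above 1. These tiles too were the extremes of 16567, and the intervals are not adjusted for that selection. The first held 32 NPC 5hmC reads over 20 input reads against 11 over 20 in ESC. For the second, all deposited reads gave 35 over 73 in NPC and 27 over 63 in ESC, so that the higher value rested on the removal of stacked reads. The remaining tiles reached 1.94 on chromosome 5 (127825001 to 127830000), 1.92 on chromosome 15 (87805001 to 87810000) and 1.91 on chromosome 7 (137460001 to 137465000), with intervals that included 1.

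The highest ESC enrichment among named tiles lay on chromosome 15 in 2 adjacent tiles. From 76005001 to 76010000 it was 14.6-fold (9.50 to 23.5) from 451 reads, and from 76010001 to 76015000 it was 10.7-fold (7.05 to 16.9). NPC reached 1.83-fold (0.891 to 3.57) and 2.43-fold (1.27 to 4.55) there, with NPC/ESC ratios of 0.0236 (0.0101 to 0.0542) and 0.0429 (0.0196 to 0.0939). Tiles on chromosome 8 (123090001 to 123095000), chromosome 5 (140445001 to 140450000) and chromosome 11 (60290001 to 60295000) were enriched 10.6-fold, 10.0-fold and 9.11-fold in ESC, with NPC/ESC ratios of 0.0389, 0.0309 and 0.0484. Over the surrounding 1 Mb on chromosome 15, from 75800001 to 76800000, the NPC/ESC ratio was 0.0858 (0.0797 to 0.0924).

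**Figure D4:**
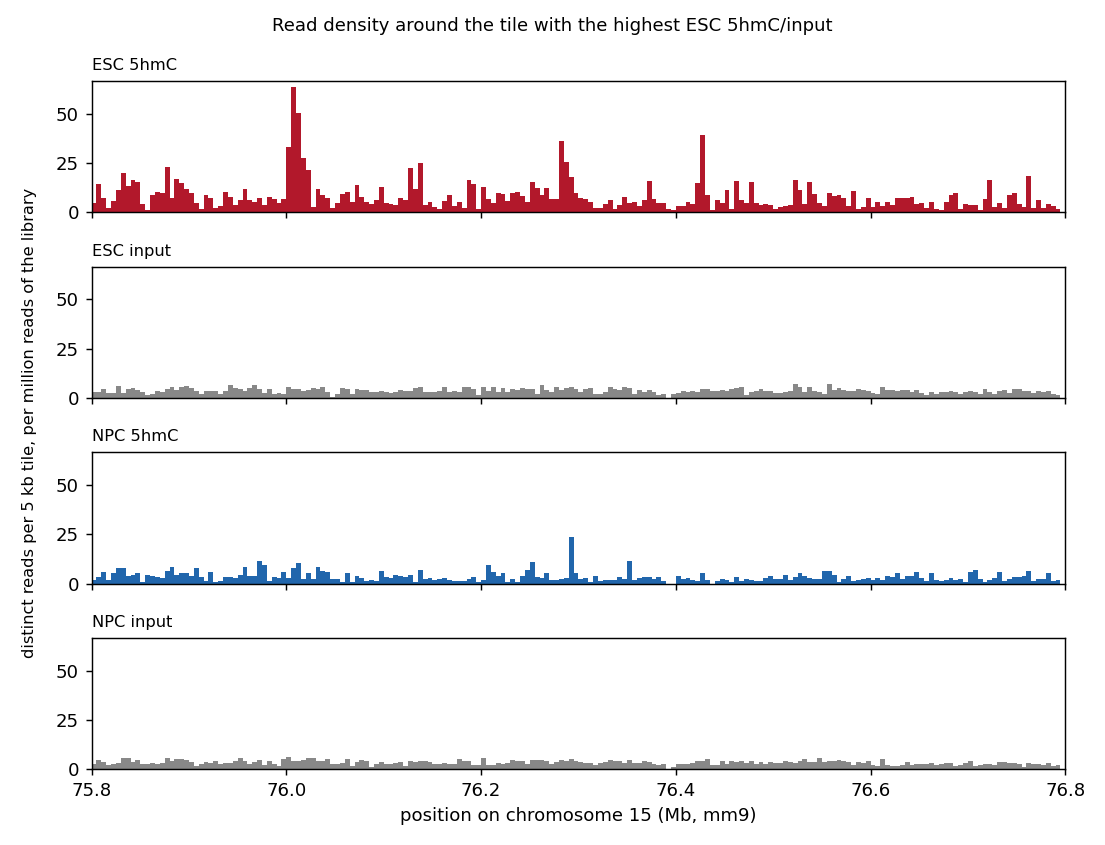
Distinct reads per 5 kb tile, scaled to the reads of each library (RPM), from 75.8 to 76.8 Mb of chromosome 15 in the 4 libraries. The ESC 5hmC library peaks at 63.3 RPM and the NPC 5hmC library at 23.5 RPM, while the inputs stay at or below 7.31 RPM; scaling by library hides the genome-wide difference.

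The highest NPC enrichment among named tiles was 15.3-fold (10.5 to 23.0) on chromosome 5 from 112055001 to 112060000, from 138 reads over 34 input reads. ESC were enriched 3.72-fold there (2.503 to 5.69), and the NPC/ESC ratio was 0.776 (0.434 to 1.38). On chromosome X from 166435001 to 166440000 NPC were enriched 12.6-fold (8.87 to 18.2) and ESC 2.76-fold (2.05 to 3.79), with a ratio of 0.857 (0.531 to 1.39). On chromosome 4 from 136365001 to 136370000 the values were 12.5-fold (7.75 to 20.9), 3.02-fold (1.92 to 4.93) and 0.778 (0.388 to 1.56). Those on chromosome 1 (154420001 to 154425000) and chromosome 7 (51610001 to 51615000) were enriched 10.6-fold and 9.83-fold in NPC. All 5 intervals of the NPC/ESC ratio included 1. In the first 3 tiles the reads were unequal between strands in both cell types. The plus strand held 18.8%, 86.4% and 19.7% of the NPC 5hmC reads and 31.2%, 81.8% and 28.4% of the ESC 5hmC reads. In the tiles on chromosomes 1 and 7 it held 64.4% and 75% in NPC and 64.55% and 66.7% in ESC. Unequal strands were not limited to tiles rich in NPC. In the 5 tiles with the highest ESC enrichment the plus strand held from 55.25% (chromosome 5) to 68.6% (chromosome 15) of the ESC 5hmC reads.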

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

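Chromosome 2 and chromosome 7 drew attention because their 5hmC per input lay on opposite sides of the genome-wide level in the cell types, beyond counting error; the difference was not tested, since each group held 1 library. Chromosome 2 stood at 0.986 of the genome-wide level in ESC (0.982 to 0.990) and at 1.01 in NPC (1.01 to 1.02). With distinct reads it stood at 1.01 in ESC (1.01 to 1.01) and 1.001 in NPC (0.995 to 1.01). The position with most reads in each of the 4 libraries lay on this chromosome, with up to 307 reads. Chromosome 7 stood at 1.03 in ESC (1.03 to 1.04) and at 0.989 in NPC (0.982 to 0.996), and at 1.03 and 0.990 with distinct reads.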

How the results depend on the processing

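The genome-wide NPC/ESC ratio stayed near its value of 0.187: it was 0.188 with distinct reads and 0.187 both without repeat-dense tiles and over all chromosomes. Of 40 chromosome values, 37 stayed within their interval with distinct reads. The others were the 5hmC ratio of chromosome 2 (0.186) and chromosome 11 (0.164) and the input ratio of chromosome 2 (0.998). The tile counts depended on the settings. Counts at other tile sizes come from other numbers of tiles, so that they were not on the same scale. In all, 47 of 91 alternative counts stayed within 1.5 times the main one. The following are those that did not, given in the order of tiles enriched in ESC, in NPC and in both, then tiles lower and higher in NPC around 1, then lower and higher around the genome-wide ratio. Tiles of 1 kb (1170555 kept) gave 128304, 7286, 4092, 124115, 1308 and 81366, without a change beyond 1.5 times in the last. As shares, 10.96% were enriched in ESC and 0.622% in NPC, against 10.6% and 5.82% in the main setting. Tiles of 20 kb (125048 kept) gave 9749, 6096, 1746, 12293, 95, 4635 and 2631, with 7.796% enriched in ESC and 4.875% in NPC. A fold of 1.5 gave 81544 tiles in ESC, 18012 in both, 89268 lower and 1429 higher around 1, and 51274 lower around the genome-wide ratio. A fold of 3 gave 19334, 14381, 2426, 20872, 198, 9415 and 6373. Without a minimum of 5hmC reads, 66650 tiles were enriched in NPC and 52174 in ESC, with 9495 higher around 1 and 45508 higher around the genome-wide ratio. A minimum of 20 reads left 4964 in NPC, 2626 in both, 79 higher around 1 and 3285 higher around the genome-wide ratio. A pseudocount of 5 reads gave 31802 in ESC beside 31523 in NPC, 259 higher around 1, and 7978 lower around the genome-wide ratio, so that 14.6% of enriched tiles lay below that ratio and 33.6% above it, against 41.9% and 21.0%. This split was 28.3% and 43.3% without a read minimum, 53.6% and 6.55% with a minimum of 20, and 61.9% and 7.85% in tiles of 1 kb. Tiles higher in NPC around 1 numbered 400 with summed inputs and 1840 with all libraries thinned to equal depth. The number of tiles, the fold threshold and the read minimum move these counts by construction. So does the pseudocount, which was added to counts from libraries of unequal depth. The cause of the other shifts was not tested. Chosen after seeing the data, windows of 1 Mb (2501) gave 81, 5, 2, 83, 0, 1 and 1. Also chosen then was leaving out tiles with over 75% of 5hmC reads on 1 strand, which kept all 7 counts within 1.5 times. That rule used the 5hmC reads of both cell types summed, at least 10 per tile. Tiles skewed in the NPC library alone can remain, so that it does not show how the NPC counts depend on them. A minimum of 10 in place of 5 reads for calls on part of the reads, also chosen after seeing the data, moved the ratio in the other part from 0.634 to 0.731 for tiles higher in NPC. The share lower in NPC around 1 was 84.8% in the main setting, and between 63.5% (no read minimum) and 95.6% (minimum of 20) over the settings chosen before the data were examined. Other settings for gene regions, gene lists and genomic features were not run, because no mm9 annotation was used here. No paired analysis was possible because each group holds 1 library, and no replicate could be left out. Depth limits the NPC 5hmC library most, at 3.63 distinct reads per tile.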

Other observations

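The tests on the fall of the NPC/ESC ratio were chosen after the result was seen; those on strands and on tiles higher in NPC were set before their results, on patterns noticed in these data.

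Mitochondrial DNA and chromosome Y were outside the comparisons above. On mitochondrial DNA 0.218 5hmC reads were obtained per input read in ESC (0.205 to 0.233) and 0.234 in NPC (0.215 to 0.254), an NPC/ESC ratio of 1.07 (0.964 to 1.19). It was thus not detectably different between cell types, while the nuclear genome was 5.34-fold lower in NPC. On chromosome Y the values were 0.331 (0.312 to 0.351) and 0.160 (0.149 to 0.171), with a ratio of 0.484 (0.442 to 0.530).

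The NPC/ESC ratio fell from ESC-poor to ESC-rich tiles. Sorting on noisy counts is argued against as the cause, since with reads not used for sorting the ratio of the poorest bin was still 4.60 times that of the richest. A second explanation is a nonspecifically bound share, equal in both barcodes because they shared a tube, on top of a larger fall of 5hmC. Such a share would bring the cell types closer together in the poorest bin, where the ratio was 0.512. Its absence predicts no particular ratio there, so that this value cannot decide and the explanation stays open. If that share were as large as the NPC level of the poorest bin (0.160 reads per input read), subtracting it from both would move the genome-wide ratio from 0.187 to 0.0852. Subtracting the level on mitochondrial DNA (0.224 over both cell types) would give 0.0364, but the 5th percentile of NPC windows of 1 Mb, 0.175, lies below that level. A larger loss of 5hmC at ESC-rich sites during differentiation remains open and was not tested apart from this.

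In tiles with at least 20 reads, the 5hmC libraries held reads mostly on 1 strand more often than the inputs. Over 75% of reads lay on 1 strand in 20.6% of 4971 NPC 5hmC tiles (19.5 to 21.8) and 4.64% of 118508 ESC 5hmC tiles (4.52 to 4.76), against 1.53% and 1.30% in the ESC and NPC inputs. The read minimum keeps far fewer tiles in NPC, so that the 2 shares cover unlike tiles. In enriched tiles with an NPC/ESC ratio over 0.5 they were 27.4% in NPC and 11.3% in ESC. At a ratio of at most 0.1 they were 5.26% (of 38 tiles) and 2.40%. The binomial shares, which depend on the reads per tile, differed as well. In ESC they were 0.816% at a ratio over 0.5 and 0.156% at a ratio of at most 0.1. The ESC share was thus 13.9 and 15.5 times the binomial one, and that excess was not larger at the high ratio. In NPC it was 27.5 and 4.27 times the binomial one. Counting error is argued against, since the NPC share of 20.6% was 18.7 times the binomial one. Mapping that favours a strand is argued against too. In the NPC tiles with reads mostly on 1 strand, 48.6% of the input reads lay on the strand richer in NPC 5hmC reads. The ESC 5hmC library favoured the same strand in 92.8% of 1001 such tiles (91.0 to 94.3), which is consistent with binding to a sequence that differs between strands, such as simple repeats in the denatured DNA, though no sequence was examined, the strand of a read is taken as that of the bound DNA, and 5hmC on a single strand is not excluded. The NPC/ESC ratio was 0.515 (0.502 to 0.528) in these tiles and 0.365 (0.3603 to 0.370) in other tiles with at least 20 NPC 5hmC reads, so that part of the NPC enrichment might not be symmetric 5hmC.

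Tiles called at least 2-fold higher in NPC may owe that call to counting error in thinly covered tiles. Tiles called so on a random part of the reads had a ratio of 0.634 in the other part with a minimum of 5 5hmC reads for the call, and 0.731 (0.678 to 0.789) with a minimum of 10, which was added after the first value was seen. These are not the 695 tiles called on all reads, whose calls rest on more reads, so that higher 5hmC in NPC in single tiles among them is not excluded. Tiles picked as extremes on part of the reads fall back in the rest even where truly raised, so that a ratio under 1 there cannot decide. Both ratios, 0.634 and 0.731, lay above the genome-wide 0.188 with distinct reads. Binomial draws with that single ratio in every tile gave 5 tiles at least 2-fold higher in NPC. Counting error around that ratio alone thus falls short of the 695.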
